A study of Homo sapiens with 6 samples.

How the data were processed

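RNA of SH-SY5Y cells, a human neuroblastoma line, was measured on 6 Affymetrix Human Gene 2.0 ST arrays, per the labels' protocols and the series' design text. The 3 groups were mock treatment with the solvent methanol, securinine at 30 µM and 16F16 at 4 µM, each for 24 h and each with 2 arrays. Total RNA was extracted with a column kit and turned into biotinylated cDNA, per the labels' protocols. The labels call the arrays of a group biological replicates and do not say how the cultures were separated. P-values therefore measure the spread between these samples.

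The authors deposited log2 expression values for 53617 probe sets on each array, with no missing value. RMA and limma are named in the submitters' processing notes, without versions or settings. RMA corrects background, normalizes between arrays and summarises the probes of a probe set, so values are relative within the set of arrays and a change shared by most genes would be removed. Scanner files and detection calls were not used here, so a probe set near background could not be told from one with low expression by a call. Of the genes picked by the naming rule, ERP27, MT1B, MT1L, MT1M and PTGS2 lay at or below the lower quartile of all probe sets on at least 4 arrays. The annotation release and the genome build of the array are not given in the sources used here. Filters before deposit are not given there either.

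Probe sets were named through a table pairing them with the platform annotation. Of the 53617 probe sets, 16098 (30.0%) had 1 gene symbol, 0 had several and 37519 were unnamed there. All 16098 were matched by Entrez identifier to a RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. That table was used for names, gene types and neighbouring genes, and none of its coordinates is given. The named probe sets covered 14884 genes, among them 11916 protein-coding genes, 1398 long noncoding RNA genes and 1072 microRNA genes. For the 779 genes with several probe sets, the one with the highest mean over the 6 arrays was taken. NQO1, the gene named in the title of the series, is not analysed here.

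Each gene was tested with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes on the deposited log2 values of all 6 arrays with group as the only term. The model had 3 residual degrees of freedom and a prior of 2.68 degrees of freedom. The comparisons made from it were securinine against mock, 16F16 against mock and 16F16 against securinine. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 14884 genes, and a gene was called at an adjusted p under 0.05. An error after a log2 difference is the standard error (SE) of the fit, and an error after a group mean is the standard deviation (SD) of 2 arrays. The number of arrays limits the precision, and the median SE of a difference was 0.11 on the log2 scale.

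Before the data were examined, 21 gene lists, the design, the naming rule and the alternatives were fixed. The lists held 595 genes, of which 332 (55.8%) were measured. The lists were NRF2 targets, heat shock response, ATF4 and integrated stress response, endoplasmic reticulum (ER) chaperones and ER-associated degradation, and the protein disulfide isomerase (PDI) family with ER thiol oxidases. Others were metallothioneins and zinc export, p53 targets, cholesterol synthesis and uptake, proteasome subunits, autophagy and lysosome, DNA replication and S phase, mitosis and G2/M phase, noradrenergic neuroblastoma identity, and mesenchymal neuroblastoma cells. The remaining lists were epithelial, blood and endothelial markers, hypoxia and glycolysis, immediate-early and inflammatory genes, interferon-stimulated genes, the mitochondrial respiratory chain, GABA-A and glycine receptor subunits, and ferroptosis and iron handling. Lists with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01, adjusted over the 19 lists tested. The proteasome list had 1 measured member and the GABA-A and glycine receptor list had 0, so neither was tested. Camera was repeated with an estimated correlation, and fry was run as a further list test. Camera asks whether a list moved one way on balance against the other genes, and fry asks whether its genes moved one way on balance by themselves. Rises and falls within a list cancel in both tests, so a list that did not pass may still hold many changed genes.

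The genes named per treatment were the 12 largest rises and the 12 largest falls among called genes whose 2 treated arrays both lay beyond both mock arrays, leaving out symbols that start as those of microRNA, small nuclear, small nucleolar, Cajal body, Y, signal recognition or small ribosomal RNA genes, uncharacterised loci, immune receptor segments and olfactory receptors, and leaving out antisense genes and pseudogenes. SNAR genes have none of these prefixes and were kept. Up to 4 members of each list with the lowest adjusted p were also named, whether or not they passed. For 16F16 against securinine, the 8 largest each way and up to 2 members per list were named. A gene outside this rule is said to have been chosen after its values were seen.

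The test was tried on simulated data, with 200 genes changed per treatment by known sizes among 14884 genes. Each gene's variance was drawn from the fitted prior and genes were drawn independently, so the results hold under the assumptions of the model. For securinine against mock, 4.48% of genes changed by 0.5 on the log2 scale were recovered, 76.1% of those changed by 1 and 98.5% of those changed by 2, with 5 false calls among 124. For 16F16 against mock the shares were 4.48%, 77.6% and 92.4%, with 9 false calls among 125. For 16F16 against securinine they were 14.2%, 79.9% and 97.0%, with 17 false calls among 271. In the simulated securinine comparison a shifted list gave a camera p of 1.7e-26, and 6 of 200 unshifted lists had p under 0.05.

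Because both treatments were set against the same mock arrays, 100 sets of unchanged groups against shared controls were simulated for every measure of overlap. A split of the mock group would leave 1 array on each side, so none was made. Alternatives were the fit of 4 arrays alone, the replicate number as a block, an intensity trend or a robust prior, array weights, a signal filter, the mean of a gene's probe sets, all probe sets, 3 scalings, stricter thresholds and leaving out each array. Protein-coding genes alone was an alternative added after the data were examined. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.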

Results

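Gene expression was measured in SH-SY5Y, a human neuroblastoma line that carries features of sympathetic neurons, after 24 h with 1 of 2 compounds or the solvent. The labels call both compounds inhibitors of protein disulfide isomerase (PDI), an enzyme that forms and rearranges disulfide bonds in the endoplasmic reticulum (ER). Securinine, a plant alkaloid, was given at 30 µM and 16F16 at 4 µM, so the doses differed. Each group had 2 arrays, and the median log2 value of an array lay between 4.16 and 4.23 over 53617 probe sets. Arrays of a group correlated across probe sets at 0.990 (mock), 0.990 (securinine) and 0.986 (16F16), and arrays of different groups at 0.979 to 0.986. The first principal component held 50.2% of the variance and separated securinine from mock, the second held 20.5% and set 16F16 apart, and the third held 11.9% and separated the 2 16F16 arrays.

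The first question was what securinine changed against mock. GDF15, a secreted stress cytokine, rose by 3.92 ± 0.14 on the log2 scale (SE, n = 2 arrays per group), a 15.1-fold rise. FAT1, a large atypical cadherin, rose by 2.95 ± 0.096, and the AP-1 subunit FOSL1 by 2.51 ± 0.25. The kinase PLK2 rose by 2.51 ± 0.14 and the immediate-early transcription factor EGR1 by 2.34 ± 0.094. CXCR4, a chemokine receptor, fell by 3.50 ± 0.20, and TXNIP, an arrestin-like protein that binds thioredoxin, fell by 3.42 ± 0.12. Further large rises were CD68 (2.18 ± 0.20) and GPNMB (2.09 ± 0.23), both lysosomal membrane glycoproteins, TFPI2 (2.00 ± 0.12), DRAM1 (2.00 ± 0.17), the long noncoding RNA PURPL (1.90 ± 0.16), the receptor EDA2R (1.84 ± 0.092) and the neuropeptide precursor VGF (1.77 ± 0.074). The receptor tyrosine kinase KIT fell by 2.84 ± 0.28, MAP2K6, a kinase upstream of p38, by 2.73 ± 0.15, and the transcription factor MYC by 2.62 ± 0.18. Chromogranin CHGA fell by 2.22 ± 0.092, the dopamine-forming decarboxylase DDC by 2.05 ± 0.12, FJX1 by 1.95 ± 0.10, the histamine receptor HRH3 by 1.93 ± 0.088, INSM2 by 1.92 ± 0.079, NHS by 1.84 ± 0.11 and CNTNAP5 by 1.81 ± 0.20. Adjusted p-values of these 24 genes in limma lay between 0.0011 and 0.0057. In total 2823 of 14884 genes passed with securinine, 1251 higher and 1572 lower, and 105 and 216 of them by at least 2-fold. Over all 53617 probe sets the balance turned, with 1426 higher and 1073 lower, and quantile normalization gave 1098 higher and 1818 lower genes. Leaving out an array lowered the count to 658 without mock replicate 1, 629 without mock replicate 2, 701 without securinine replicate 1 and 974 without securinine replicate 2.

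The p53, heat shock, NRF2 and autophagy lists were shifted up by camera with securinine. Of 14 measured p53 targets, genes induced by the tumour suppressor p53, 10 rose and 0 fell, among them EDA2R, PLK2, TP53INP1 (1.49 ± 0.078) and the exonuclease AEN (1.28 ± 0.075). Adjusted over the list alone 13 rose, and camera gave an adjusted p of 7.3e-12 (adjusted p = 0.12 with an estimated correlation). Of 14 heat shock genes, 10 rose and 0 fell (12 adjusted over the list alone), including the HSP90 co-chaperone CHORDC1 (0.95 ± 0.085), BAG3 (0.66 ± 0.080), and the HSP70 genes HSPA1A (0.85 ± 0.088) and HSPA1B (0.84 ± 0.089). HSPA1A and HSPA1B are near-identical copies, so their separate values are uncertain. The camera adjusted p was 6.8e-08 for heat shock genes (adjusted p = 0.099 with an estimated correlation). Of 22 NRF2 targets, genes of the response to oxidants and electrophiles, 13 rose and 1 fell, the same counts as adjusted over the list alone. They included the autophagy receptor SQSTM1 (1.47 ± 0.080), RIT1 (1.35 ± 0.11), the sulfiredoxin SRXN1 (1.20 ± 0.087) and the thioredoxin reductase TXNRD1 (1.13 ± 0.084). The NRF2 list had a camera adjusted p of 2.4e-05 (adjusted p = 0.099 with an estimated correlation). Of 24 autophagy and lysosome genes, 10 rose and 0 fell (11 adjusted over the list alone), with the lysosomal channel MCOLN1 at 0.93 ± 0.096, LAMP1 at 0.70 ± 0.083 and ATG16L1 at 0.51 ± 0.077. That list had a camera adjusted p of 1.6e-06 (adjusted p = 0.099 with an estimated correlation).

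The ER chaperone list was shifted up by camera with securinine, and the PDI family and ATF4 lists did not pass. Of 17 ER chaperone and ER-associated degradation genes, 6 rose and 0 fell (8 adjusted over the list alone), among them the sensor kinase ERN1 (0.58 ± 0.090), calreticulin CALR (0.57 ± 0.075), the chaperone HYOU1 (0.50 ± 0.084) and SEC11C (0.50 ± 0.082). Camera gave an adjusted p of 0.0020 for it (adjusted p = 0.25 with an estimated correlation). Of 17 genes of the PDI family and ER thiol oxidases, ERP44 rose by 0.48 ± 0.092 and TMX1 fell by 0.36 ± 0.076, with the same 1 and 1 adjusted over the list alone. The 15 others did not pass, and ERP27 was at 0.18 ± 0.097 and TXNDC12 at 0.17 ± 0.097. The PDI family was not shifted by camera (adjusted p = 0.70), and its median was -0.030 and its mean 0.024. In the ATF4 and integrated stress response list of 28, 5 rose and 10 fell (6 and 10 adjusted over the list alone). GDF15, the transcription factor DDIT3 (1.67 ± 0.11) and SESN2 (1.52 ± 0.11) rose, and the serine synthesis enzyme PSAT1 fell by 1.11 ± 0.079. Camera gave an adjusted p of 0.45 for this list, whose called genes went both ways, and its median was -0.17 and its mean 0.017.

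The DNA replication, mitosis and noradrenergic lists were shifted down by camera with securinine, and the immediate-early list up. Of 25 DNA replication and S phase genes, 14 fell and 0 rose (17 fell adjusted over the list alone). The helicase subunits MCM7, MCM3 and MCM6 fell by 0.89 ± 0.077, 0.70 ± 0.074 and 0.68 ± 0.082, and cyclin CCNE1 fell by 0.77 ± 0.092. This list had a camera adjusted p of 2.4e-06 (adjusted p = 0.25 with an estimated correlation). Of 28 mitosis genes, 6 fell and 0 rose (10 fell and 1 rose adjusted over the list alone), with KIF20A at -0.48 ± 0.089, AURKB at -0.42 ± 0.097, TOP2A at -0.41 ± 0.093 and TTK at -0.37 ± 0.083. The mitosis list had a camera adjusted p of 0.049 (adjusted p = 0.71 with an estimated correlation). Its call was lost without mock replicate 1 (adjusted p = 0.12), mock replicate 2 (0.058), securinine replicate 2 (0.22) or either 16F16 replicate (0.058), and with the replicate block (0.053). Of 19 genes of noradrenergic neuroblastoma identity, 9 fell and 2 rose (10 and 3 adjusted over the list alone), including CHGA, DDC, the receptor RET (-1.30 ± 0.12) and the transcription factor GATA2 (-1.01 ± 0.10). That list had a camera adjusted p of 0.0022 (adjusted p = 0.37 with an estimated correlation). Of 21 immediate-early and inflammatory genes, 6 rose and 2 fell (8 and 2 adjusted over the list alone). EGR1 and FOSL1 rose, and MYC and the phosphatase DUSP6 (-0.96 ± 0.15) fell. Camera gave an adjusted p of 0.033 for the immediate-early list (adjusted p = 0.25 with an estimated correlation), and the call was lost without mock replicate 2 (adjusted p = 0.089) or securinine replicate 2 (0.071).

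The other lists were not shifted by camera with securinine. Of 10 metallothionein and zinc export genes, MT1X fell by 1.40 ± 0.11 and MT2A by 0.80 ± 0.15 (also 2 adjusted over the list alone). MT1M (-0.47 ± 0.17, at or below the lower quartile of all probe sets on 5 of 6 arrays) and MT1F (-0.90 ± 0.41) did not pass, and the camera adjusted p was 0.052. The list passed camera without mock replicate 2 (adjusted p = 0.011), securinine replicate 1 (0.042) or either 16F16 replicate (0.043), and with the replicate block (0.019). These genes are close paralogs, so single values are uncertain. Among 17 cholesterol genes 1 rose and 4 fell, also when adjusted over the list alone, and the camera adjusted p was 0.70. IDI1 rose by 0.62 ± 0.095, and INSIG1, FDPS and DHCR7 fell by 0.52 ± 0.089, 0.50 ± 0.089 and 0.43 ± 0.095. Among 17 hypoxia and glycolysis genes 1 rose and 4 fell (2 and 7 adjusted over the list alone), with a camera adjusted p of 0.11. Hexokinase HK2 fell by 1.06 ± 0.092, NDRG1 by 0.71 ± 0.13 and BNIP3 by 0.38 ± 0.088, and EGLN1 rose by 0.46 ± 0.089. Among 15 mesenchymal genes 4 rose and 0 fell (4 and 1 adjusted over the list alone), namely CD44 (0.71 ± 0.094), SNAI2 (0.63 ± 0.12), FOSL2 (0.56 ± 0.080) and TWIST1 (0.36 ± 0.089), with a camera adjusted p of 0.12. Among 17 interferon-stimulated genes RIGI (0.69 ± 0.10) and IRF9 (0.59 ± 0.10) rose and USP18 fell by 0.63 ± 0.11, also when adjusted over the list alone. IFIT1 was at -0.85 ± 0.24 without passing, with both securinine arrays below the lower quartile of all probe sets. The camera adjusted p of the interferon list was 0.66. Camera turned up for that list, and its median was 0.017 and its mean -0.019. Among 8 ferroptosis and iron genes, heme oxygenase HMOX1 rose by 1.26 ± 0.19, and LPCAT3 and PCBP1 fell by 0.59 ± 0.085 and 0.37 ± 0.080. The counts were 1 and 2 adjusted over the list alone, PTGS2 was at -0.20 ± 0.086, the camera adjusted p was 0.66, the median was -0.13 and the mean 0.0056. None of 9 respiratory chain genes passed in limma (1 at an unadjusted p under 0.05), also adjusted over the list alone, with UQCRC1 at -0.29 ± 0.082 and a camera adjusted p of 0.66. Of 11 epithelial, blood and endothelial markers, CD14 passed at 0.57 ± 0.14, and 0 passed adjusted over the list alone. PECAM1 was at -0.54 ± 0.19, with both securinine arrays below the lower quartile of all probe sets, and EPCAM was at -0.19 ± 0.12. The camera adjusted p of this marker list was 0.96, with camera turned up and the median at -0.037. The proteasome assembly gene POMP, the measured member of its list, rose by 0.36 ± 0.091.

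**Figure D1:**
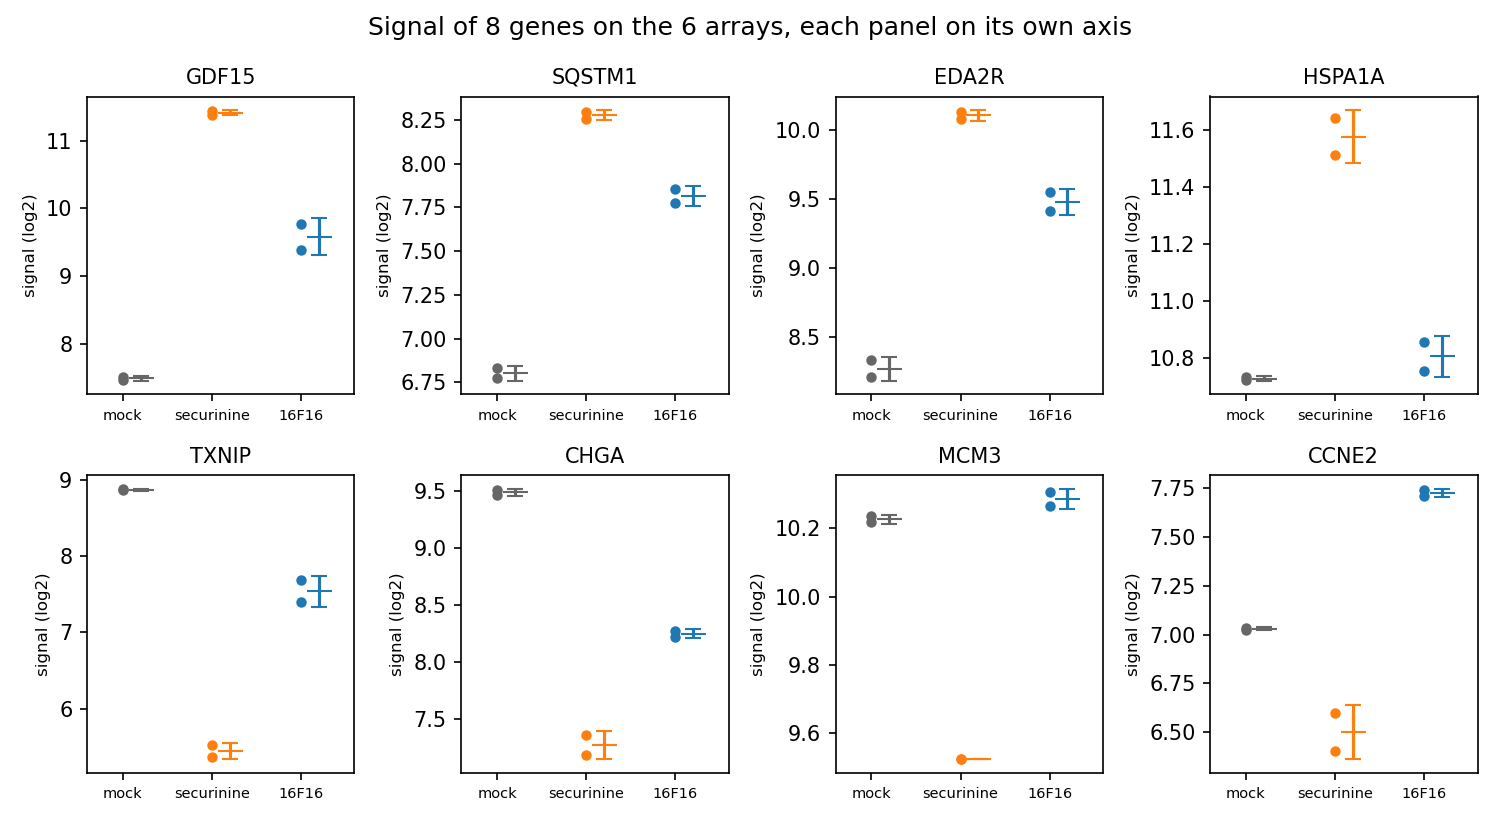
Log2 signal of 8 genes (vertical axis, a separate range in each panel) on the 2 mock, 2 securinine and 2 16F16 arrays. Points are arrays, and bars beside them are the mean ± SD of 2 arrays. GDF15 rose by 3.92 with securinine and by 2.09 with 16F16, and CCNE2 was lower than mock with securinine (-0.53) and higher with 16F16 (0.70).

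The second question was what 16F16 changed against mock. GDF15 rose by 2.09 ± 0.14 on the log2 scale (SE, n = 2 arrays per group), a 4.26-fold rise, and the muscle ankyrin repeat gene ANKRD1 by 1.64 ± 0.17. FAT1 rose by 1.40 ± 0.096, EDA2R by 1.22 ± 0.092 and SQSTM1 by 1.01 ± 0.080. NEUROG2, a proneural transcription factor, fell by 1.89 ± 0.13, the ephrin EFNB2 by 1.65 ± 0.15 and MYC by 1.65 ± 0.18. Other large rises were TFPI2 (1.17 ± 0.12), PLK2 (1.15 ± 0.14), ITPKB (1.12 ± 0.098), the biliverdin reductase BLVRB (1.11 ± 0.11), PURPL (1.05 ± 0.16), the kinesin KIF1C (1.05 ± 0.086) and ABHD4 (0.99 ± 0.12). CNTNAP5 fell by 1.55 ± 0.20, the growth factor HGF by 1.52 ± 0.15, TXNIP by 1.33 ± 0.12 and FGF14 by 1.27 ± 0.10, and INSM2 was 2.82-fold lower. The small noncoding RNA genes SNAR-B1 (-1.32 ± 0.14), SNAR-H (-1.28 ± 0.093), SNAR-C1 (-1.26 ± 0.15) and SNAR-D (-1.26 ± 0.16) are near-identical copies and their separate values are uncertain. Adjusted p-values of these 24 genes in limma lay between 0.024 and 0.049. In total 223 of 14884 genes passed with 16F16, 107 higher and 116 lower, and 18 and 34 of them by at least 2-fold. Centring each array on its median gave 101 higher and 99 lower. With limma 3139 genes had an unadjusted p under 0.05, and leaving out any 1 of mock replicates 1 and 2, securinine replicates 1 and 2 or 16F16 replicates 1 and 2 gave 0 called genes, with 2099 to 2904 at an unadjusted p under 0.05. The count was 1808 with an intensity trend in the variance prior, and the fit of the 4 arrays of these groups alone called 0 genes, with 2904 at an unadjusted p under 0.05. Leaving out a securinine array amounts to that fit, since the differences of 16F16 from mock stay the same and only the estimate of the spread changes.

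The p53, NRF2, autophagy and ER chaperone lists were shifted up by camera with 16F16, and the heat shock and PDI family lists did not pass. Of 14 p53 targets, 8 rose and 0 fell (10 adjusted over the list alone), including EDA2R, PLK2, the apoptosis gene BAX (0.69 ± 0.088) and AEN (0.67 ± 0.075). Camera gave an adjusted p of 5.4e-10 for them (adjusted p = 0.20 with an estimated correlation). Of 22 NRF2 targets, 4 rose and 0 fell (8 adjusted over the list alone), namely SQSTM1, BLVRB, TXNRD1 (0.64 ± 0.084) and SRXN1 (0.61 ± 0.087). The NRF2 list had a camera adjusted p of 4.1e-05 (adjusted p = 0.20 with an estimated correlation). Of 24 autophagy and lysosome genes, SQSTM1 rose and 0 fell (4 rose adjusted over the list alone). MCOLN1 at 0.58 ± 0.096, LAMP1 at 0.38 ± 0.083 and CTSD at 0.32 ± 0.077 did not pass, and camera gave an adjusted p of 0.00068 (adjusted p = 0.20 with an estimated correlation). None of 17 ER chaperone genes passed in limma (4 at an unadjusted p under 0.05), and 4 rose adjusted over the list alone. ERN1 was at 0.58 ± 0.090, the value that was called with securinine, so a missing call with 16F16 is not by itself a difference between the compounds. CRELD2 was at 0.47 ± 0.077, SEC11C at 0.37 ± 0.082 and CALR at 0.31 ± 0.075. For the ER chaperone list camera gave an adjusted p of 0.00088 (adjusted p = 0.31 with an estimated correlation). None of 14 heat shock genes passed in limma (2 at an unadjusted p under 0.05), also adjusted over the list alone, with BAG3 at 0.29 ± 0.080, HSPD1 at -0.26 ± 0.081, STIP1 at -0.15 ± 0.095 and HSPB8 at 0.16 ± 0.10. The camera adjusted p of the heat shock list was 0.66. None of 17 genes of the PDI family passed in limma (1 at an unadjusted p under 0.05), also adjusted over the list alone, with TMX4 at 0.24 ± 0.087, QSOX1 at 0.18 ± 0.075, TXNDC12 at -0.20 ± 0.097 and ERO1B at 0.18 ± 0.10. Camera gave an adjusted p of 0.78 for the PDI family.

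The DNA replication and mesenchymal lists were shifted up by camera with 16F16, and the hypoxia and glycolysis, mitosis and noradrenergic lists down, each with 0 to 4 genes that passed. Of 25 DNA replication genes 2 rose, namely cyclin CCNE2 (0.70 ± 0.094) and the replication licensing factor CDT1 (0.58 ± 0.088), and 0 fell. Adjusted over the list alone 7 rose and 3 fell, MCM7 (-0.47 ± 0.077) and E2F1 (0.43 ± 0.076) did not pass over all genes, and camera gave an adjusted p of 0.0043 (adjusted p = 0.37 with an estimated correlation, and 0.057 without 16F16 replicate 1). Of 17 hypoxia and glycolysis genes, HK2 fell by 0.97 ± 0.092 and PGAM1 by 0.76 ± 0.097, and 0 rose (9 fell adjusted over the list alone). BNIP3 at -0.47 ± 0.088 and PGK1 at -0.39 ± 0.086 did not pass, and camera gave an adjusted p of 4.2e-06 (adjusted p = 0.32 with an estimated correlation). Of 28 mitosis genes, the kinase PLK1 fell by 0.64 ± 0.084 and 0 rose (8 fell and 1 rose adjusted over the list alone). CCNB1 was at -0.63 ± 0.099, KIF20A at -0.56 ± 0.089 and AURKA at -0.52 ± 0.10, and camera gave an adjusted p of 0.00010 (adjusted p = 0.37 with an estimated correlation). Of 19 noradrenergic genes, CHGA fell by 1.24 ± 0.092, RET by 1.17 ± 0.12, DDC by 1.06 ± 0.12 and CHGB by 0.81 ± 0.097, and 0 rose (7 fell and 1 rose adjusted over the list alone). That list had a camera adjusted p of 3.1e-05 (adjusted p = 0.32 with an estimated correlation). None of 15 mesenchymal genes passed in limma (4 at an unadjusted p under 0.05), and 1 rose adjusted over the list alone. SNAI2 was at 0.61 ± 0.12, FN1 at 0.44 ± 0.12, VIM at 0.28 ± 0.095 and CD44 at 0.27 ± 0.094, and camera gave an adjusted p of 0.045 (adjusted p = 0.32 with an estimated correlation). The mesenchymal call was lost without mock replicate 2 (adjusted p = 0.10), 16F16 replicate 1 (0.070) or 16F16 replicate 2 (0.081), and with the replicate block (0.057).

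The other lists were not shifted by camera with 16F16. In the ATF4 list of 28, GDF15 and SESN2 (0.78 ± 0.11) rose and VLDLR (-0.65 ± 0.079) and PSAT1 (-0.59 ± 0.079) fell, with 3 rising and 6 falling adjusted over the list alone and a camera adjusted p of 0.074. Of 21 immediate-early genes EGR1 rose by 0.95 ± 0.094 and MYC fell, with 2 rising and 3 falling adjusted over the list alone and a camera adjusted p of 0.33. JUN at -0.58 ± 0.095 and IER3 at 0.50 ± 0.087 did not pass, and 5 of 11 probe sets of IER3 had that sign. Of 17 interferon-stimulated genes RIGI rose by 0.70 ± 0.10, also adjusted over the list alone, and IRF9 (0.33 ± 0.10) and MX2 (-0.67 ± 0.23) did not pass. Camera turned up for that list with an adjusted p of 0.84, and its median was -0.043. In limma 0 of 10 metallothionein, 17 cholesterol, 8 ferroptosis and 11 epithelial, blood and endothelial genes passed, also adjusted over the list alone, and 3, 7, 1 and 0 had an unadjusted p under 0.05. Camera adjusted p-values for these were 0.96, 0.66, 0.52 and 0.99, and the last list was turned up with a median of -0.00019. MT1B lay at a log2 signal of 1.76 to 2.79, at or below the lower quartile of all probe sets on 6 of 6 arrays, so it was not shown to be above background. Values of the others included MT1X at -0.38 ± 0.11, FDPS at -0.34 ± 0.089, HAMP at -0.36 ± 0.11 and CLDN4 at -0.47 ± 0.29. Of 9 respiratory chain genes 0 passed in limma (2 at an unadjusted p under 0.05), and 1 fell adjusted over the list alone, with UQCRC2 at -0.33 ± 0.074, UQCRC1 at -0.24 ± 0.082 and a camera adjusted p of 0.052. POMP was at 0.068 ± 0.091.

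The third question was how the compounds differed from each other, at unequal doses. CXCR4 was 2.52 ± 0.20 higher on the log2 scale with 16F16 than with securinine (SE, n = 2 arrays per group), TXNIP 2.09 ± 0.12 and KIT 1.65 ± 0.28. GDF15 was lower with 16F16 (-1.83 ± 0.14), as were FOSL1 (-1.73 ± 0.25), FAT1 (-1.55 ± 0.096) and EGR1 (-1.39 ± 0.094). MAP2K6 (1.56 ± 0.15), GALM, an enzyme of galactose metabolism (1.49 ± 0.099), the proteoglycan VCAN (1.41 ± 0.083), EXPH5 (1.38 ± 0.16) and the retrotransposon-derived imprinted gene RTL1 (1.37 ± 0.13), which overlaps several microRNA genes, were higher. KRTAP5-2 (-1.44 ± 0.20), GPNMB (-1.40 ± 0.23), PLK2 (-1.36 ± 0.14) and EFNB2 (-1.34 ± 0.15) were lower. Adjusted p-values of these 16 genes in limma lay between 0.0088 and 0.028. In total 1416 genes differed, 826 higher and 590 lower with 16F16, and 97 and 33 of them by at least 2-fold. Quantile normalization gave 1009 higher and 489 lower, centring each array on its median 841 and 434, and among genes above the median signal the balance turned, with 1454 higher and 1494 lower. The count was 324 without mock replicate 1, 324 without mock replicate 2 and 261 without 16F16 replicate 2. It was 0 in limma without securinine replicate 1, securinine replicate 2 or 16F16 replicate 1, with 3023, 3290 and 3469 genes at an unadjusted p under 0.05.

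The DNA replication and metallothionein lists were shifted up by camera with 16F16 against securinine, and the heat shock, p53, autophagy and NRF2 lists down. Of 25 DNA replication genes 14 were higher and 0 lower (24 higher adjusted over the list alone), led by CCNE2 (1.23 ± 0.094) and CDT1 (1.11 ± 0.088). The list median was 0.41, and camera gave an adjusted p of 7.2e-13 (adjusted p = 0.16 with an estimated correlation). Of 14 heat shock genes 9 were lower and 0 higher (13 adjusted over the list alone), with CHORDC1 at -0.90 ± 0.085 and HSPA1A at -0.77 ± 0.088, and camera gave an adjusted p of 3.4e-09 (adjusted p = 0.13 with an estimated correlation). Of 14 p53 targets 8 were lower and 0 higher (10 adjusted over the list alone), with PLK2 and TP53INP1 (-0.89 ± 0.078), and camera gave an adjusted p of 2.3e-08 (adjusted p = 0.16 with an estimated correlation). Of 24 autophagy and lysosome genes 3 were lower and 0 higher (10 lower and 1 higher adjusted over the list alone), including ATG16L1 (-0.52 ± 0.077) and SQSTM1 (-0.46 ± 0.080). Camera gave an adjusted p of 0.0026 for them (adjusted p = 0.16 with an estimated correlation). Of 22 NRF2 targets 8 were lower and 1 higher (10 and 3 adjusted over the list alone), with RIT1 at -0.79 ± 0.11 and BLVRB, the higher member, at 1.16 ± 0.11. The NRF2 list had a camera adjusted p of 0.0075 (adjusted p = 0.16 with an estimated correlation). Of 10 metallothionein and zinc export genes 2 passed as higher and 0 as lower (3 higher adjusted over the list alone). They were MT1X (1.02 ± 0.11) and MT1B, which was not shown to be above background, and camera gave an adjusted p of 0.016 (adjusted p = 0.19 with an estimated correlation).

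The remaining lists did not differ by camera between the compounds. None of 17 genes of the PDI family passed in limma (5 at an unadjusted p under 0.05), and 2 were higher and 2 lower adjusted over the list alone. TMX1 was at 0.33 ± 0.076 and TMX4 at 0.33 ± 0.087, and camera gave an adjusted p of 0.89. None of 17 ER chaperone genes passed in limma (6 at an unadjusted p under 0.05), also adjusted over the list alone, with SDF2L1 at 0.34 ± 0.081, HYOU1 at -0.35 ± 0.084 and a camera adjusted p of 0.41. In the ATF4 list 7 of 28 were higher and 4 lower (7 and 5 adjusted over the list alone), with GDF15 and ATF4 itself (-0.81 ± 0.077) among the lower and a camera adjusted p of 0.89. CHGA (0.98 ± 0.092) and DDC (2.00-fold) were among 4 higher and 2 lower noradrenergic genes of 19 (4 and 5 adjusted over the list alone), with a camera adjusted p of 0.50. AURKA (-0.74 ± 0.10) and CCNB1 (-0.49 ± 0.099) were the 2 lower of 28 mitosis genes, also adjusted over the list alone, with a camera adjusted p of 0.47. EGLN1 (-0.83 ± 0.089) and ANKRD37 (-0.58 ± 0.11) were among 3 lower of 17 hypoxia genes (1 higher and 5 lower adjusted over the list alone), with a camera adjusted p of 0.090. EGR1 and JUN (-0.69 ± 0.095) were among 3 lower and 1 higher of 21 immediate-early genes (4 and 1 adjusted over the list alone), with a camera adjusted p of 0.11. FN1 (0.87 ± 0.12) was higher and FOSL2 (-0.61 ± 0.080) among 2 lower of 15 mesenchymal genes (2 and 2 adjusted over the list alone), with a camera adjusted p of 0.89. INSIG1 (0.56 ± 0.089) was higher and STARD4 (-0.44 ± 0.087) lower among 17 cholesterol genes (2 and 1 adjusted over the list alone), with a camera adjusted p of 0.43. LPCAT3 (0.51 ± 0.085) was higher and HMOX1 (-1.21 ± 0.19) lower among 8 ferroptosis genes (2 and 1 adjusted over the list alone), with a camera adjusted p of 0.95. In limma 0 of 17 interferon-stimulated, 9 respiratory chain and 11 epithelial, blood and endothelial genes passed, also adjusted over the list alone, and 3, 2 and 2 had an unadjusted p under 0.05. Camera adjusted p-values for these were 0.89, 0.41 and 0.95. Their values included USP18 at 0.46 ± 0.11, UQCRC2 at -0.29 ± 0.074 and CD14 at -0.52 ± 0.14, and POMP was at -0.30 ± 0.091. Camera turned down for interferon-stimulated genes and for the epithelial, blood and endothelial list, and their medians were 0.029 and 0.037.

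**Figure D2:**
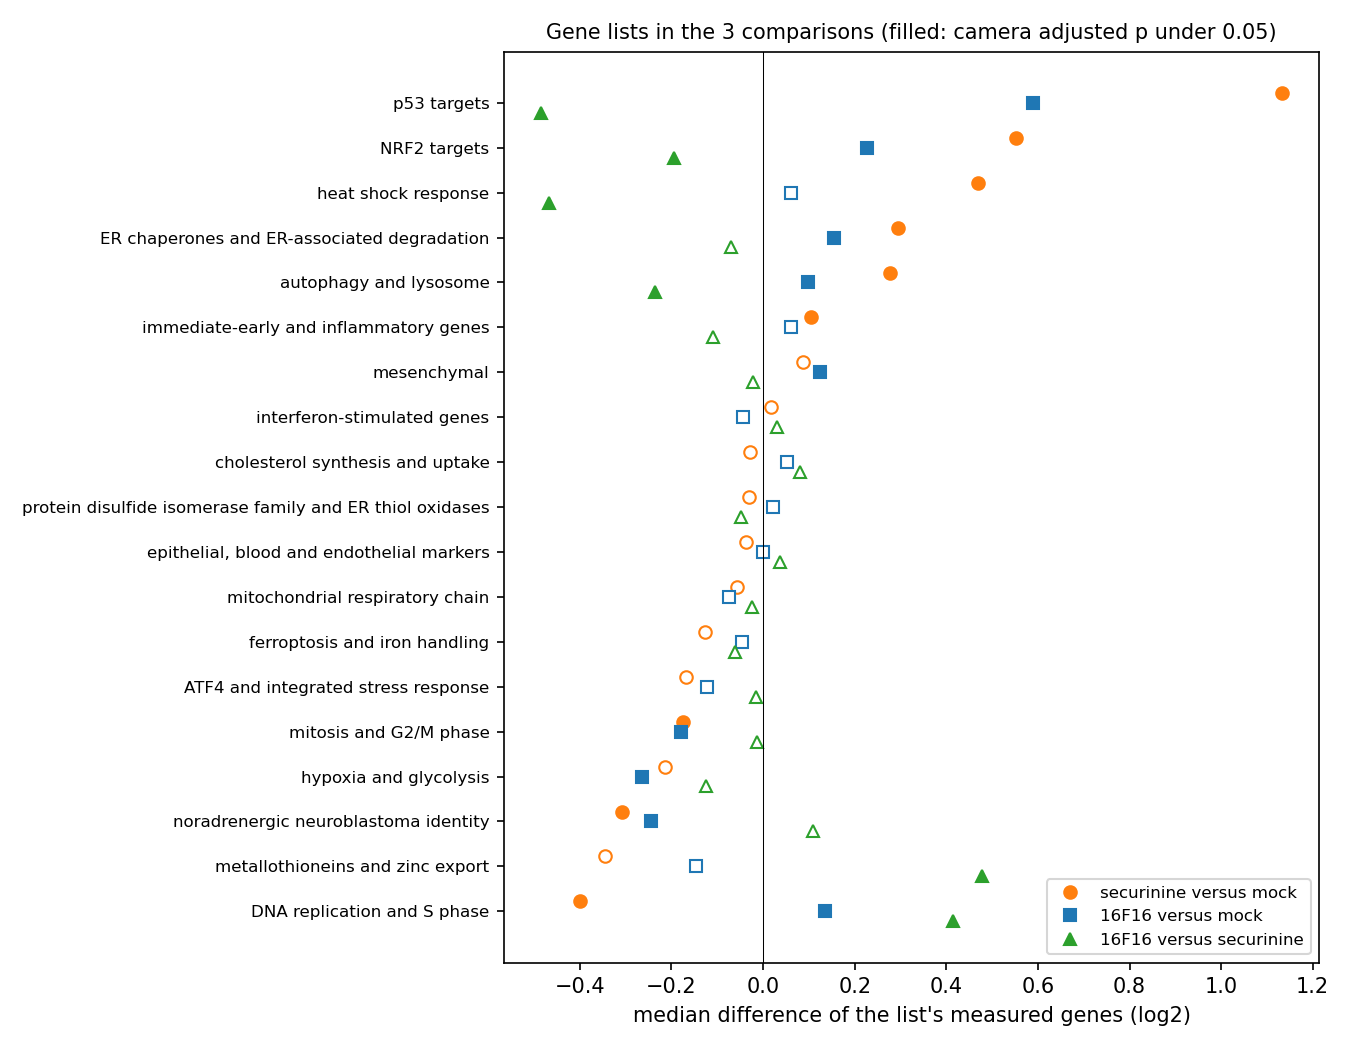
Median log2 difference over the measured genes (horizontal axis) of 19 gene lists (vertical axis). Circles are securinine against mock, squares 16F16 against mock and triangles 16F16 against securinine, and filled symbols are lists with a camera adjusted p under 0.05 at the preset correlation. The DNA replication list lay at -0.40 with securinine and at 0.14 with 16F16.

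The last question was how far the compounds changed the same genes. GDF15, FAT1, PLK2, EDA2R, TFPI2 and PURPL were among 87 genes that rose with both compounds, and MYC, TXNIP, CHGA, INSM2 and CNTNAP5 among 99 that fell with both. Independent lists of these sizes would share 9.0 and 12.3 genes, a number that leaves out the shared mock arrays. Simulated unchanged groups against shared mock arrays shared 0 called genes in limma, a number that leaves out real effects. CCNE2 and CDT1 passed with both compounds in opposite directions. Across all genes, which are not independent replicates, the log2 differences of the compounds correlated at 0.580, against 0.499 in simulated groups (0.469 to 0.522 over 100 simulations). Their covariance was 0.0565 against a simulated 0.0142, a difference of 0.0423. Part of the excess of shared calls over independent lists may come from the shared mock arrays. In limma 0 genes passed with both compounds when any 1 array was left out, since 16F16 then had no called gene.

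**Figure D3:**
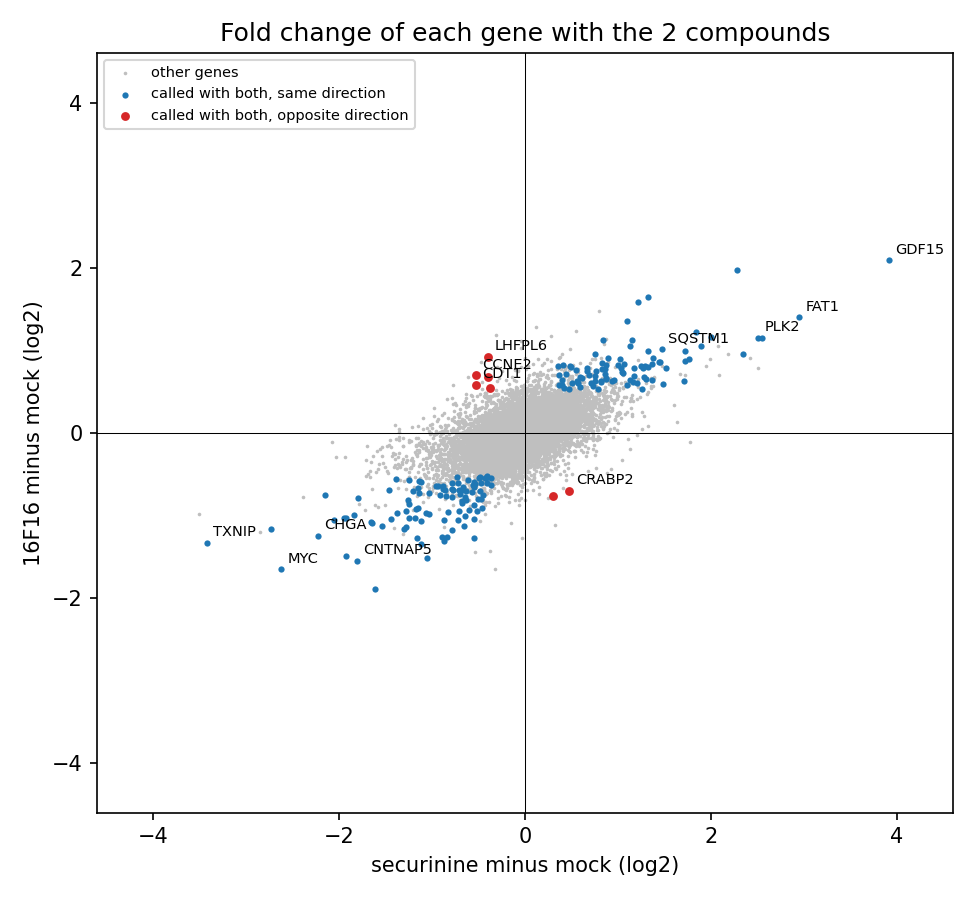
Log2 difference of each of 14884 genes with securinine (horizontal axis) and with 16F16 (vertical axis), both against mock. Points are genes, with 186 that passed with both compounds in the same direction in blue, 7 in opposite directions in red and the others in grey. GDF15 lies farthest to the upper right, at 3.92 and 2.09.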

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

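The test of a single response that differs only in strength was chosen after the result was seen, as were the 5 genes named here besides CCNE2 and CDT1 and the separate test of unnamed probe sets. That cyclic loess moved too little to decide was also judged after its results were seen. The other tests in this part were chosen before their results were seen, on patterns noticed in these data.

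Against mock 7 genes were called in opposite directions with the compounds. Their direct differences also passed in limma, which follows from how they were picked and adds no support. CCNE2, a cyclin of S phase entry, was at -0.53 with securinine and 0.70 with 16F16, a difference of 1.23 (adjusted p = 0.0088). CDT1, which licenses replication origins, was at -0.53 and 0.58, a difference of 1.11 (adjusted p = 0.0088). LHFPL6 differed by 1.32, the growth factor binding protein IGFBP5 by 1.07 and SPMIP4 by 0.92, each lower with securinine and higher with 16F16. The retinoic acid binding protein CRABP2 (-1.18) and MIR1224 (-1.07) went the other way. The calls of these 7 genes against mock with 16F16 were lost without any 1 of the 6 arrays. Leaving out a securinine array does not change the differences of 16F16 from mock. The loss there came from the estimate of the spread on fewer arrays, not from the values of that array. The direct calls were lost without securinine replicate 1, securinine replicate 2 or 16F16 replicate 1, where limma called 0 genes and 3023, 3290 and 3469 had an unadjusted p under 0.05.

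The DNA replication list was shifted down with securinine and up with 16F16 by camera, with a median difference of 0.41 between the compounds over 25 genes. After cyclic loess the list passed camera with an adjusted p of 3.2e-14. Loess moved no gene of that comparison by over 0.089, so it could not decide on normalization between arrays. A bias of normalization that follows signal level falls under the test on random lists that comes next. Of 10000 random lists matched on signal, 0% had a median difference as high (the highest was 0.24), and the highest adjusted p without 1 array was 2.3e-10, which argue against a bias that follows signal level and against 1 aberrant array. The random lists and the fits without 1 array concerned only the difference between the compounds, which the fall with securinine alone could carry. They do not decide whether 1 array carried the rise with 16F16 against mock. Without any 1 array the list median with 16F16 stayed between 0.12 and 0.14, but its camera call was lost without 16F16 replicate 1. All camera calls of the list were lost with an estimated correlation, between the compounds (adjusted p = 0.16), with securinine (0.25) and with 16F16 (0.37). Of the 25 genes, 16 were below mock with securinine and above it with 16F16. Another 6 were below mock with both, namely MCM7 (-0.47 with 16F16), UNG (-0.33), MCM6 (-0.32), GINS3 (-0.24), MCM2 (-0.045) and MCM5 (-0.020). Compound and dose changed together, no test separated them, and no biological explanation was tested.

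Fold changes of the compounds against mock went together across genes, with 186 genes called in the same direction. The covariance was 0.0565, above the highest of 100 simulations with shared mock arrays (0.0151). The simulations drew each gene and array independently with the spread within groups. They argue against such noise of the mock arrays as the whole source. A deviation common to both mock cultures would not appear in them and stays open. Whether a single response differs only in strength stays open. Against it stood 1 fixed list, DNA replication, which fry moved down with securinine (adjusted p = 0.0016), up with 16F16 (adjusted p = 0.026) and up between them (adjusted p = 0.0017). That list had already been seen to move in opposite directions by camera, so fry on the same arrays adds little. Camera with an estimated correlation gave an adjusted p of 0.37 for the list with 16F16. Its call with 16F16 by fry held without 16F16 replicate 2 (adjusted p = 0.049) and was lost without any 1 of the other 5 arrays (adjusted p 0.053 to 0.12), and in limma 0 genes departed from a change with 16F16 at 0.38 of that with securinine, with 2730 at an unadjusted p under 0.05. Whether a shared response comes from PDI inhibition was not tested.

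Probe sets without a gene name were left out of the comparisons, and 37519 of them were tested separately with limma. Of these, 650 changed with securinine, 460 higher and 190 lower. With 16F16 1 was higher than mock, and 1 was lower with 16F16 than with securinine, while 4181 and 5396 had an unadjusted p under 0.05.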

How the results depend on the processing

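Protein-coding genes alone was chosen after the data were examined, and the other alternatives before. No named gene that was called, before or under an alternative, reversed its direction under the alternatives run. Counts are given for securinine, 16F16, 16F16 against securinine, and genes called with both compounds in the same direction, which were 2823, 223, 1416 and 186. The 4 arrays of the groups compared gave 2462, 0, 324 and 0. Arrays with the same number did not deviate together (correlations of deviations -0.032, 0.038 and -0.050), and the replicate block gave 2066, 0, 503 and 0. An intensity trend in the variance prior gave 4129, 1808, 3107 and 1230, genes above the median signal 3829, 1737, 2948 and 1217, and protein-coding genes alone 3182, 611, 1934 and 444. Of the genes named with 16F16, 26 gained a call with the trend and 68 kept theirs or stayed uncalled. The signal filter added a call for 28 and left 49 as they were, while the replicate block took the call from 42 and left 52. All probe sets gave 2499, 0, 0 and 0, with more features to adjust over. At least 2-fold left 321, 52, 130 and 36, and adjusted p under 0.01 left 863, 0, 104 and 0, both by construction. In limma the counts of 0 stood beside 2904 genes with 16F16 at an unadjusted p under 0.05 on 4 arrays, 2856 with the block, 7250 and 9565 with all probe sets, and 3139 at the stricter threshold. Leaving out 1 array gave 629 to 2462 for securinine, 0 for 16F16, 0 to 324 for 16F16 against securinine and 0 for both compounds, with a lone array assumed to vary like the other groups. The lowest securinine counts were 629 and 658 without mock replicates 2 and 1, and 701 and 974 without securinine replicates 1 and 2. The direct count was 0 without securinine replicate 1 or 2 or 16F16 replicate 1, 261 without 16F16 replicate 2, and 324 without mock replicate 1 or 2. Robust prior, array weights, the mean of probe sets and the 3 scalings kept each count within 1.5 times. Lists shifted numbered 9, 9 and 6, and 0, 0 and 0 with an estimated correlation in camera, while fry gave 13, 9 and 7 and leaving out 1 array 7 to 11, 8 to 9 and 6 to 7, of which 7 to 9, 7 to 9 and 6 were among those 9, 9 and 6. Lists gained without 1 array were metallothioneins and hypoxia with securinine, ATF4 and respiratory chain with 16F16, and hypoxia and immediate-early genes between the compounds. Other causes were not tested. The alternatives planned for NQO1 were not run.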

Other observations

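The gene families, windows and single genes in this part were chosen after the data were examined, as were the tests on the 14q32 members above the median signal and the judgement that cyclic loess moved too little to decide. The other tests on the whole 14q32 cluster were chosen before their results were seen.

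TXNIP had a close relative that fell with it, since the arrestin-like gene ARRDC4, which like TXNIP is induced by glucose-sensing transcription factors, fell by 1.65 ± 0.099 with securinine (SE, limma adjusted p = 0.0018). With 16F16 ARRDC4 was at -0.36 ± 0.099 and did not pass (adjusted p = 0.13), and it was 1.29 ± 0.099 higher with 16F16 than with securinine (adjusted p = 0.0088). Among 180 families of at least 10 genes that share the start of their symbol, 3 passed camera with securinine, 3 with 16F16 and 1 between the compounds. HOXD genes, developmental transcription factors that lie together, had a median of -0.57 with securinine (camera adjusted p = 0.0060, adjusted p = 0.94 with an estimated correlation). Of 10 HOXD genes, HOXD13 fell by 1.58 ± 0.22, HOXD9 by 1.04 ± 0.17, HOXD8 by 0.66 ± 0.15 and HOXD1 by 0.50 ± 0.086. With 16F16 their median was -0.36 and 0 passed in limma, with 7 at an unadjusted p under 0.05 (camera adjusted p = 0.0076, adjusted p = 1.0 with an estimated correlation).

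Genes of the small mitochondrial ribosome subunit, named MRPS, had a median of -0.23 with securinine, where 8 of 26 fell, among them MRPS34 (-0.50 ± 0.092) and MRPS18B (-0.47 ± 0.090). Their camera adjusted p was 0.010 (adjusted p = 0.94 with an estimated correlation). With 16F16 the median was -0.17 and 0 passed in limma, with 9 at an unadjusted p under 0.05 (camera adjusted p = 0.026, adjusted p = 1.0 with an estimated correlation). RNA binding motif genes, named RBM, went up with securinine, where 11 of 40 rose and 1 fell, among them RBM33 (0.57 ± 0.10) and RBM4B (0.49 ± 0.078). The RBM family had a camera adjusted p of 0.0039 (adjusted p = 0.94 with an estimated correlation). With 16F16 against securinine 6 RBM genes were lower and 0 higher, with a median of -0.16 (camera adjusted p = 0.0081, adjusted p = 0.91 with an estimated correlation). Of 15 ABHD hydrolase genes, ABHD4 (0.99 ± 0.12) and ABHD2 (0.62 ± 0.088) rose with 16F16, and camera gave an adjusted p of 0.013 (adjusted p = 1.0 with an estimated correlation). Symbol families also take in antisense genes and pseudogenes, such as HOXD-AS2, RBM5-AS1 and MRPS31P5. None of these medians changed sign under cyclic loess, quantile normalization or median centring. Those scalings moved values by 0.018 to 0.019 on average, too little to turn medians of this size, so the check adds no support. Of 746 windows of up to 20 neighbouring measured genes, 0 passed camera in any comparison, with 50, 56 and 42 at an unadjusted p under 0.05.

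RTL1 and microRNA genes that lie inside it had far lower signal with securinine, namely RTL1 (-1.59 ± 0.13), MIR136 (-2.39 ± 0.13), MIR432 (-2.15 ± 0.081), MIR431 (-2.03 ± 0.13) and MIR127 (-1.93 ± 0.12). These genes overlap, and whether their probes read separate transcripts was not tested. With 16F16 MIR432 fell by 0.75 ± 0.081 (limma adjusted p = 0.030). MIR136 (-0.78 ± 0.13), MIR127 (-0.29 ± 0.12), MIR431 (-0.29 ± 0.13) and RTL1 (-0.22 ± 0.13) were lower with 16F16 and did not pass. Over the 57 measured genes of the surrounding 14q32 imprinted cluster, most of them dim, 2 fell and 0 rose with 16F16. With securinine, to which the values below belong, 10 fell and 0 rose. Their median was -0.080 (bootstrap -0.14 to 0.023), and camera in limma gave an unadjusted p of 0.067. The 8 above the median signal had a median of -1.76 (bootstrap -2.15 to -0.33), and 6 of them fell. These 8 were mostly RTL1 and the microRNA genes named above, so that median describes their locus rather than the cluster. The others were DLK1 (-0.94 ± 0.11), which fell, and MIR2392 (-0.33 ± 0.11, limma adjusted p = 0.10) and MEG9 (0.015 ± 0.11, limma adjusted p = 0.95), which did not pass. A fall of microRNA probe sets as a class is argued against by a median of 0.020 over 1019 other microRNA genes and of -0.049 over the 121 above the median signal (bootstrap -0.079 to 0.046). Loss of a chromosome segment that reaches the neighbours is argued against by a median of 0.17 over the 28 neighbouring genes above the median signal (bootstrap 0.00088 to 0.31). Cyclic loess (6 of the 6 falls still passed, and the median of the 57 was -0.055) moved no gene by over 0.029, so it could not decide on normalization between arrays. A bias of normalization that follows signal level would move other bright genes too. The medians of -0.049 and 0.17 over such genes argue against it for RTL1 and the microRNA genes inside it. Those genes were matched only by lying above the median signal. A loss confined to the cluster was not tested (the median of all 50 neighbours, 0.032, did not decide on a loss either).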
